A study of Arabidopsis thaliana with 24 samples.

How the data were processed

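Total RNA from roots and shoots of Arabidopsis was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 24 arrays in 8 groups of 3. Per the file headers, the scanner files hold the intensity of each spot on a linear scale from Agilent Feature Extraction 10.7.3.1, each array on its own. The processed signal in them is the mean pixel signal after detrending, with substitute values for spots near background. The deposited value table of the series holds log2 values, which were found to be quantile normalized over the 24 arrays and centred per probe, with column medians between -0.03 and 0.02. The authors' processing notes name RMA, limma and R 2.12.1 without saying what each did. Each column of that table matched the array of another sample, so the table was not used for any result.

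Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged. No spot was saturated. The value analysed was log2 of the processed signal minus the 75th percentile of the array. For a locus with several probes, which was so for 97 loci, the probe with the highest mean over all arrays was used. A gene was tested in a tissue where its probe was well above background on all 3 arrays of at least 1 group of that tissue. Probes were named by locus in the files, and 32781 loci had a probe. Symbols came from a reference table of another genome build, so no coordinates are printed. A gene not well above background on every array of a group has only a bound there. The bound sets the brighter group's mean against, on each array of the dimmer group, the higher of the lowest signal among probes well above background and the probe's own signal.

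The tests were run in R 4.3.3 with limma 3.58.1 (lmFit, contrasts and eBayes), with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for reading files and drawing. Each tissue had its own fit of 12 arrays and 4 groups, and the comparison between tissues used all 24 arrays. There were 11 comparisons: the drought response of each genotype, the genotype difference in each condition and their interaction, in each tissue, and the WT response in roots against shoots. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested.

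Gene lists, 24 in all with 352 genes, were fixed before the data were examined, and lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01. Adjustment ran over all lists and the 10 comparisons within a tissue, and separately for the comparison between tissues. Beside it stood camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance. Of 240 list tests within a tissue, 70 were called at the preset correlation, 0 with an estimated correlation and 49 by fry, 37 of these shared with camera. Calls shared with fry were counted by adjusted p alone, without comparing the direction. Both called 9 lists in the WT and 11 in the NIC3OX drought response of roots, and 5 and 6 in those of shoots. Between genotypes both called 1 list in control roots, 0 in drought roots, 2 in control shoots and 2 in drought shoots. In the interactions both called 0 in roots and 1 in shoots. The lists were NAD metabolism, ABA synthesis and breakdown, clade A PP2C, PYR/PYL receptors, drought transcription factors, LEA and dehydration proteins, proline metabolism, raffinose synthesis, aquaporins, heat shock, antioxidant enzymes, photosynthesis, cell wall expansion, suberin, cuticular wax, senescence, jasmonate, salicylate and defence, cell cycle, circadian clock, iron homeostasis, nitrate assimilation, root tissue markers and reference genes.

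The genes named were, per comparison, the 10 largest rises and 10 largest falls among called genes with a symbol, groups that do not overlap array by array, and a signal well above background on every array of the higher group. From each list up to 4 members with the smallest adjusted p could be named, with NCED3, RD29A, RD29B, RAB18, P5CS1 and NAD genes where a sentence is about them, and NIC3 and NIC2 always. That rule was set before the data were examined, and a selection of those genes is printed. A list of 19 pollen genes and a list of 9 floral organ identity genes were written after pollen transcripts had been noticed and before their values were computed. AGP11 was taken off the pollen list before that, because it had already been seen to vary.

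Alternatives changed 1 choice at a time: normexp background correction with an offset of 50, quantile normalization, no filter and a strict filter on dim probes, the mean of all probes of a gene, the replicate number as a block, only the arrays compared or all 24 arrays in 1 fit, and each array left out in turn. Added after the data were seen were the pollen list as a covariate, the arrays without VGDH2 signal left out, and the lists with each array left out. Arrays lay on 3 slides, scanned slide by slide, and the replicate number equalled the slide number on 24 of 24 arrays, so slide, scan and number form 1 block. Each slide held 1 array of every group, with WT in 1 row and NIC3OX in the other. Every group lay at the same position on each slide, with control and drought arrays in different columns. Position is therefore confounded with group.

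The fit was tested on simulated data with the spread of each gene taken from the real arrays and 200 changed genes per comparison. Each gene was given the same spread in every group, so the effect of unequal spread between groups was not tested. Of changes of 1 on the log2 scale between 55% and 81% were recovered, and of changes of 2 between 79% and 97%, with between 3 and 15 unchanged genes called per comparison. In a simulation of 24 lists, the 1 list moved by 1 was called and 0 others were. Genes were simulated independently of each other and the lists drawn at random. The effect of correlation between the genes of a list was therefore not tested. Random steps used seed 7.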

Results

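Roots and shoots of Arabidopsis thaliana (Col-0) were profiled on 1-colour Agilent arrays, with and without water withdrawal, in wild type (WT) and in plants that the labels call NIC3OX. The series title names NICOTINAMIDASE 3 (NIC3), an enzyme that releases nicotinic acid from nicotinamide in the NAD salvage pathway, and drought tolerance. The 24 arrays fell into 8 groups of 3, one for each combination of genotype, organ and condition. Each array carried 54778 spots, of which 53459 were not controls, and up to 63.9% of the spots were well above background. The sample labels give 9 days on medium and 8 on soil before treatment, against 10 and 5 in the series description, and this disagreement is not settled. They speak of biological replicates without saying whether plants were pooled for an array or grown in separate batches, so independence is not settled and the p-values below measure only the spread between these samples. The number of arrays limits the precision. Drought lasted 5 days in the series description and in the treatment text of the samples. The label of each sample also gives 5 days for all WT drought arrays, but 5, 6 and 7 days for NIC3OX drought roots 1, 2 and 3 and 8, 9 and 10 days for NIC3OX drought shoots 1, 2 and 3. These numbers rise by 1 per sample in the order in which the samples are listed, running on from roots to shoots. Whether the sample labels or the treatment text are right is not settled. If the sample labels hold, the length of drought is confounded with genotype in every comparison of NIC3OX with WT under drought and in both interactions, and it also enters the NIC3OX drought responses. Every ± below is a standard error of the fit with 3 arrays per group unless SD is named.

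The NIC3 probe was read before any comparison, because the gene names the line. In roots, NIC3 rose under drought by 1.52 ± 0.14 on the log2 scale in WT (adjusted p = 1.97e-05). In NIC3OX roots it rose from -1.01 (SD 0.11) relative to the 75th percentile of the array to 0.29 (SD 0.30), which is 2.46-fold (adjusted p = 5.04e-05). Between genotypes, NIC3 differed by -0.11 ± 0.14 in control roots (adjusted p = 0.725) and by -0.33 ± 0.14 in drought roots (adjusted p = 0.499), so the arrays labelled NIC3OX showed no higher NIC3 signal at this probe. In shoots, NIC3 was not well above background on any of the 12 arrays, of either genotype, and no fold is given. Its close copy and neighbour NIC2 fell by 0.25 ± 0.08 in WT roots under drought (adjusted p = 0.0366) and passed the test in none of the other comparisons. The part of the transcript that the NIC3 probe covers was not determined here, although the files give probe sequences. A transgene transcript that lacks that part would not be seen.

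**Figure D1:**
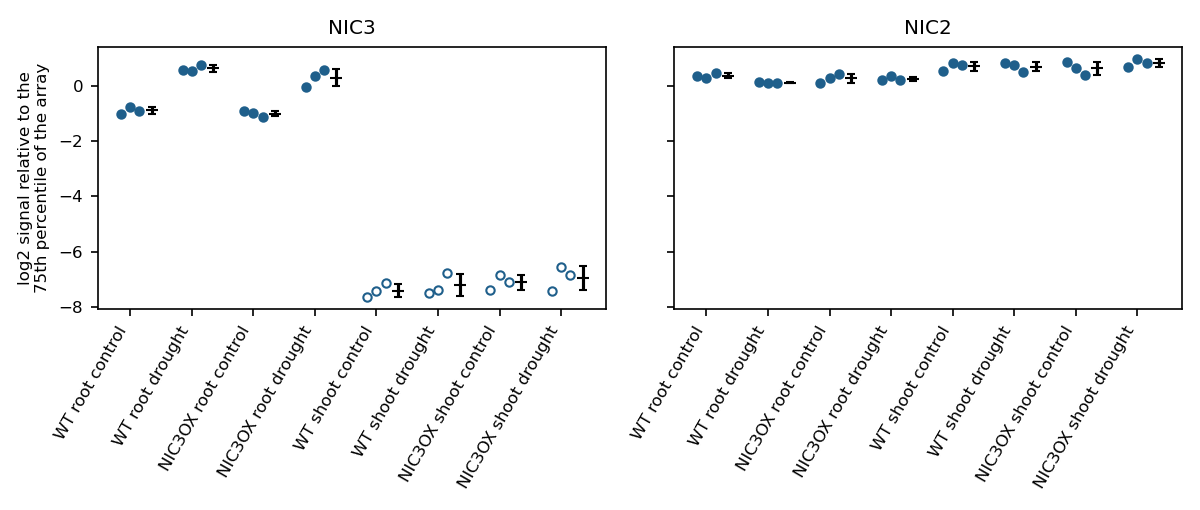
Signal of the NIC3 and NIC2 probes on every array (vertical axis, log2 relative to the 75th percentile of the array; horizontal axis, the 8 groups). Filled points were well above background, open points were not, and the bars beside them give the mean and SD of 3 arrays. The NIC3 means were -1.01 in NIC3OX control roots and -0.90 in WT control roots.

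WT roots under drought were compared with watered WT roots to see which genes drought changed. RAB18, a dehydrin, was at least 22.0-fold higher under drought (adjusted p = 3.8e-06) and was not well above background on the control arrays. TSPO, a stress-induced membrane protein, was at least 72.5-fold higher (adjusted p = 3.7e-06) and was likewise not well above background in control roots. RD29B rose by 5.13 ± 0.34 and LEA4-5 by 5.11 ± 0.32 on the log2 scale. MRN1, a triterpene synthase, rose by 7.11 ± 0.36. NCED3, which catalyses a committed step of abscisic acid (ABA) synthesis, rose by 4.02 ± 0.24. The largest falls included the reductase gene FRO5, at least 34.0-fold lower, and the metal transporter gene ZIP10, at least 20.6-fold lower, neither well above background in drought roots, and FRO4, which fell by 5.40 ± 0.80.

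Among the lists fixed beforehand, all 11 suberin genes rose in WT roots, for example KCS2 by 1.59 ± 0.19 and CYP86B1 by 1.33 ± 0.16, and the list was called (adjusted p = 2.45e-06, and adjusted p = 0.506 with an estimated correlation). Of 20 measured LEA and dehydration genes, 14 rose and 6 did not pass, or 15 rose adjusted over the list alone (adjusted p = 2.69e-08, and adjusted p = 0.245 with an estimated correlation). Of 9 clade A PP2C phosphatases, which restrain ABA signalling, 8 rose and 1 did not pass, also adjusted over the list alone, with HAI2 up by 4.80 ± 0.23 (adjusted p = 4.11e-07, and adjusted p = 0.352 with an estimated correlation). Their partners, the PYR/PYL receptors, ran the other way. Of 10 receptors 7 fell, 1 rose and 2 did not pass, also adjusted over the list alone, and PYL6 fell by 4.11 ± 0.13 (adjusted p = 0.00123, and adjusted p = 0.352 with an estimated correlation). Of 17 drought transcription factors 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, with NAC019 up by 4.04 ± 0.26 (adjusted p = 1.35e-05, and adjusted p = 0.363 with an estimated correlation). Of 12 genes of ABA synthesis and breakdown 9 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.00415, and adjusted p = 0.245 with an estimated correlation). Antioxidant enzymes rose for 9 of 20 and fell for 1, or 12 and 1 adjusted over the list alone (adjusted p = 0.00186, and adjusted p = 0.245 with an estimated correlation). Senescence genes rose for 8 of 11 and fell for 3, also adjusted over the list alone (adjusted p = 0.0388, and adjusted p = 0.518 with an estimated correlation). Jasmonate genes rose for 11 of 18, or 11 with 1 fall adjusted over the list alone, with VSP1 up by 2.07 ± 0.17 (adjusted p = 0.00124, and adjusted p = 0.556 with an estimated correlation). In total, 8219 of 22347 genes passed the limma test, 4039 higher and 4180 lower, and 10228 had an unadjusted p under 0.05.

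NIC3OX roots under drought were set against watered NIC3OX roots in the same way. LEA7 rose by 5.49 ± 0.29, LEA4-5 by 5.25 ± 0.32 and MRN1 by 6.66 ± 0.36, while RAB18 was at least 11.7-fold higher and not well above background in the control roots. LTP4, a lipid transfer protein, was at least 38.5-fold higher and also not well above background there. GSTF14 fell by 3.75 ± 0.15 and BCAT7 by 3.80 ± 0.29, and ZIP10 was at least 54.9-fold lower and not well above background in drought roots. Across genes the drought changes of both genotypes had r = 0.91, a correlation over genes, which are not independent replicates, and 3363 higher and 3392 lower calls were shared against 809.7 and 883.8 for independent lists.

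By list, 17 of 20 LEA and dehydration genes rose in NIC3OX roots, also adjusted over the list alone (adjusted p = 6.64e-09, and adjusted p = 0.245 with an estimated correlation). All 11 suberin genes rose, CYP86B1 by 1.92 ± 0.16 (adjusted p = 8.71e-08, and adjusted p = 0.483 with an estimated correlation). All 9 clade A PP2C genes rose (adjusted p = 2.37e-07, and adjusted p = 0.352 with an estimated correlation). Heat shock genes rose for 7 of 9, also adjusted over the list alone, with HSP90.1 up by 1.77 ± 0.24 and HSFA2 by 1.54 ± 0.24 (adjusted p = 0.00461, and adjusted p = 0.589 with an estimated correlation). The mean of these 9 genes was -2.33 to -1.37 on NIC3OX control arrays and -0.94 to -0.37 under drought. On WT root arrays it was -0.83 to 0.19 in control and -0.99 to -0.29 under drought. The same low NIC3OX control arrays enter this rise, the genotype difference in watered roots and the root interaction. Of 8 cuticular wax genes 4 rose, also adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.518 with an estimated correlation). Iron homeostasis genes fell for 6 of 9, also adjusted over the list alone, FRO2 by 2.52 ± 0.28 and IRT1 by 1.68 ± 0.31 (adjusted p = 0.0414, and adjusted p = 0.367 with an estimated correlation). The PYR/PYL receptors fell for 6 of 10 and rose for 2, also adjusted over the list alone (adjusted p = 0.0414, and adjusted p = 0.506 with an estimated correlation), and both the receptor and the iron calls were lost with the slide as a block. Drought transcription factors rose for 11 of 17, also adjusted over the list alone (adjusted p = 0.000139, and adjusted p = 0.367 with an estimated correlation). Genes of ABA synthesis and breakdown rose for 8 of 12 and fell for 2, also adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.352 with an estimated correlation). Antioxidant enzymes rose for 10 of 20 and fell for 2, or 12 and 2 adjusted over the list alone (adjusted p = 0.00153, and adjusted p = 0.245 with an estimated correlation). Senescence genes rose for 8 of 11 and fell for 2, also adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.506 with an estimated correlation). The test called 9205 of 22347 genes, 4480 higher and 4725 lower, with 11043 at an unadjusted p under 0.05.

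NIC3OX and WT were compared in watered roots to see what differed before drought. Heat shock genes were lower in NIC3OX. HSP70-4 fell by 2.17 ± 0.34, HSP17.6A by 1.93 ± 0.38, the heat shock factor HSFA2 by 1.86 ± 0.24, HSP17.4 by 1.65 ± 0.33 and HSP90.1 by 1.44 ± 0.24. Of 9 measured heat shock genes 5 fell and 4 did not pass, or 7 fell adjusted over the list alone, and the list median was -1.86, or -1.78, -1.63 and -1.44 within slides 1, 2 and 3 (adjusted p = 8.71e-08, and adjusted p = 0.363 with an estimated correlation). Outside that list the amino acid transporter UMAMIT14 fell by 2.07 ± 0.14 and the ammonium transporter AMT1;5 by 1.94 ± 0.29. The auxin-responsive gene SAUR29 was at least 3.75-fold higher in NIC3OX, since it was not well above background in WT, and RTFL11, a small peptide gene, rose by 0.96 ± 0.09. Of the 20 genes ranked by size in this comparison, 3 kept their call whichever array was left out.

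The other called lists in watered roots rested on small shifts. Of 16 cell wall expansion genes EXPA8 alone passed; it fell by 0.86 ± 0.15, and 2 fell adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.506 with an estimated correlation). None of 11 suberin genes passed, against 2 fallen adjusted over the list alone (adjusted p = 0.000947, and adjusted p = 0.621 with an estimated correlation). None of 8 cuticular wax genes passed, against 2 fallen adjusted over the list alone (adjusted p = 0.00694, and adjusted p = 0.506 with an estimated correlation). None of 5 nitrate genes passed, against 3 fallen adjusted over the list alone (adjusted p = 0.0495, and adjusted p = 0.556 with an estimated correlation). The jasmonate list had a median of 0.18 with 0 of 18 passing, or 1 risen adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.686 with an estimated correlation). The test called 284 of 22347 genes, 61 higher and 223 lower, and 3929 had an unadjusted p under 0.05. The count was 0 with only the arrays compared in the fit and 17 with no filter on dim probes. It was 463 without NIC3OX root control replicate 1, 14 without NIC3OX root control replicate 2, and 15, 24 and 76 without WT root control replicates 1, 2 and 3. NIC3OX root control replicate 1 also had the most spots near background, with substitute values on 37.6%.

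NIC3OX and WT were compared in drought roots. No gene passed the limma test among 22347 (2111 had an unadjusted p under 0.05), and the smallest adjusted p was 0.101. With normexp background correction 1 gene passed, and with quantile normalization 1 gene passed. The 9 heat shock genes, of which 5 passed as lower in watered roots, had a list median of -0.07 here. By the sample labels, drought lasted longer on NIC3OX replicates 2 and 3 than in WT. The jasmonate list was called lower with a median of -0.16, while 0 of 18 members passed, also adjusted over the list alone (adjusted p = 0.0343, and adjusted p = 0.71 with an estimated correlation). MYC2, the jasmonate transcription factor, differed by -0.14 ± 0.07 (adjusted p = 0.542).

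The interaction in roots asks whether the drought change differed between genotypes. RTFL11 had a log2 interaction of -1.19 ± 0.12 (adjusted p = 0.0395). Its signal went from -2.79 to -2.05 in WT and from -1.83 to -2.28 in NIC3OX. AT2G03250, named after its values were seen because it has no symbol, passed too (adjusted p = 0.0395), but was not well above background in control roots of either genotype, so no size is given. By the sample labels, the interaction also carries a difference in the length of drought. These 2 genes were all that passed among 22347, against 1368 at an unadjusted p under 0.05. The count was 0 with the slide as a block, with normexp, with quantile normalization and with no filter. It was 4 without NIC3OX root control replicate 1, 1 without NIC3OX root drought replicate 2 and 3 without NIC3OX root drought replicate 3. Of the 2 genes, these fits kept 2, 1 and 1. The count was 1 without WT root control replicate 3, and that gene was neither of the 2. It was 0 without any other array.

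Heat shock genes had the largest interaction of the lists, with a median of 1.78. None of its 9 members passed over all genes, against 6 higher adjusted over the list alone, and HSP90.1 had 1.52 ± 0.34 (list adjusted p = 6.64e-09, and adjusted p = 0.352 with an estimated correlation). Suberin had a median of 0.37 with 1 higher adjusted over the list alone (adjusted p = 4e-06, and adjusted p = 0.506 with an estimated correlation). The jasmonate median was -0.32 with 0 adjusted over the list alone (adjusted p = 2.43e-05, and adjusted p = 0.506 with an estimated correlation). Nitrate assimilation had 0.55 with 2 higher adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.367 with an estimated correlation). Cuticular wax had 0.47 with 0 adjusted over the list alone (adjusted p = 0.0136, and adjusted p = 0.524 with an estimated correlation). Raffinose synthesis had 0.27 with 1 higher adjusted over the list alone (adjusted p = 0.0392, and adjusted p = 0.363 with an estimated correlation). The PYR/PYL receptors had 0.08 with 2 higher adjusted over the list alone (adjusted p = 0.0414, and adjusted p = 0.506 with an estimated correlation). The receptor and raffinose calls were lost with the slide as a block. By fry, 0 lists were called in this interaction.

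WT shoots under drought were compared with watered WT shoots. Jasmonate genes rose: AOC1 by 3.41 ± 0.52, AOS by 2.08 ± 0.27 and LOX2 by 1.80 ± 0.33, all enzymes of jasmonate synthesis, and the responsive gene VSP2 by 2.51 ± 0.23. BFT, a relative of the flowering regulator FT, rose by 3.34 ± 0.29, and the heat shock factor HSFA2 rose by 2.54 ± 0.33. NUDT24 was at least 4.98-fold higher and not well above background in control shoots. PER4, a peroxidase, was at least 2.19-fold lower and not well above background under drought.

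Jasmonate genes rose for 10 of 20 in WT shoots, or 13 adjusted over the list alone (adjusted p = 6.64e-09, and adjusted p = 0.363 with an estimated correlation). LEA and dehydration genes rose for 8 of 18, or 9 adjusted over the list alone, with RD20 up by 2.26 ± 0.30 (adjusted p = 1.49e-06, and adjusted p = 0.363 with an estimated correlation). Heat shock genes rose for 3 of 8, or 5 adjusted over the list alone (adjusted p = 4.16e-05, and adjusted p = 0.363 with an estimated correlation). Genes of ABA synthesis and breakdown rose for 3 of 11, also adjusted over the list alone, with CYP707A4 up by 1.11 ± 0.07 (adjusted p = 0.00461, and adjusted p = 0.245 with an estimated correlation). Clade A PP2C genes rose for 3 of 7, also adjusted over the list alone, with HAI2 up by 1.22 ± 0.29 (adjusted p = 0.0151, and adjusted p = 0.506 with an estimated correlation). Of 8 cuticular wax genes KCS1 rose by 1.42 ± 0.24, and 2 rose adjusted over the list alone (adjusted p = 0.0128, and adjusted p = 0.62 with an estimated correlation). The test called 2540 of 22198 genes, 1241 higher and 1299 lower, with 6889 at an unadjusted p under 0.05. The count was 1099 and 1178 without WT shoot control replicates 2 and 3, and 1432, 1358 and 1238 without WT shoot drought replicates 1, 2 and 3. It was 4787 with all 24 arrays in 1 fit and 1494 with no filter.

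NIC3OX shoots under drought were compared with watered NIC3OX shoots. BFT rose by 3.09 ± 0.29 and PYD4 by 2.77 ± 0.26, and NAMT1 was at least 5.66-fold higher, not well above background in control shoots. GOLS2, an enzyme of raffinose synthesis, rose by 1.91 ± 0.24 and GOLS1 by 1.11 ± 0.16. The drought transcription factors HB7 and HB12 rose by 1.31 ± 0.19 and 1.07 ± 0.11. CRK30, a receptor kinase, fell by 2.99 ± 0.35, COR27 by 1.62 ± 0.19 and the flowering regulator CO by 1.18 ± 0.21. Pollen transcripts also varied between these arrays. VGDH2 was well above background on NIC3OX shoot control replicates 1 and 3 and drought replicate 2, and not on control replicate 2 or drought replicates 1 and 3.

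LEA and dehydration genes rose for 2 of 18 in NIC3OX shoots, or 8 adjusted over the list alone, LTI30 by 1.14 ± 0.18 (adjusted p = 8.71e-08, and adjusted p = 0.352 with an estimated correlation). Clade A PP2C genes rose for 3 of 7, or 6 adjusted over the list alone, HAB1 by 0.89 ± 0.14 (adjusted p = 3.94e-07, and adjusted p = 0.245 with an estimated correlation). Drought transcription factors rose for 3 of 16, or 5 adjusted over the list alone (adjusted p = 0.00379, and adjusted p = 0.556 with an estimated correlation). Genes of ABA synthesis and breakdown rose for 1 of 11, or 4 adjusted over the list alone (adjusted p = 0.000786, and adjusted p = 0.245 with an estimated correlation). Senescence genes rose for 1 of 11, or 3 adjusted over the list alone (adjusted p = 4.61e-05, and adjusted p = 0.367 with an estimated correlation). Jasmonate genes rose for 1 of 20, or 2 adjusted over the list alone (adjusted p = 0.00696, and adjusted p = 0.673 with an estimated correlation). Raffinose genes rose for 2 of 5, also adjusted over the list alone (adjusted p = 0.00924, and adjusted p = 0.342 with an estimated correlation). The aquaporin list was called higher with a median of 0.11 and 0 of 19 passing, also adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.686 with an estimated correlation). The nitrate list was called lower with a median of -0.68 and 0 of 5 passing, or 3 fallen adjusted over the list alone (adjusted p = 0.00736, and adjusted p = 0.437 with an estimated correlation). The test called 427 of 22198 genes, 284 higher and 143 lower, with 3768 at an unadjusted p under 0.05.

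That count of 427 depended on the arrays and the fit. It was 181 and 205 without NIC3OX shoot control replicates 1 and 2, and 148, 142 and 125 without NIC3OX shoot drought replicates 1, 2 and 3. It was 248 with the slide as a block, 276 with normexp, 188 with no filter, 0 with only the arrays compared and 1247 with all 24 arrays in 1 fit. The pollen list as a covariate, an alternative added after the data were seen, gave 672. The shared calls with WT shoots were 208 higher and 91 lower, against 15.9 and 8.4 for independent lists, with r = 0.44 across genes.

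NIC3OX and WT were compared in watered shoots. ERF53, a drought-linked transcription factor gene, rose by 1.81 ± 0.23 (adjusted p = 0.0434) in NIC3OX. XTH25, a cell wall enzyme gene, fell by 1.80 ± 0.23, the sugar transporter SWEET4 by 1.21 ± 0.14, RL6 by 0.98 ± 0.13 and ARR11 by 0.71 ± 0.09. Pollen transcripts differed within NIC3OX here too, since VGDH2 was not well above background on control replicate 2. The test called 14 of 22198 genes, 4 higher and 10 lower, with 3125 at an unadjusted p under 0.05. The count was 393 without NIC3OX shoot control replicate 3, 1 without WT shoot control replicate 1, and 0 without NIC3OX shoot control replicate 1 or 2 or WT shoot control replicate 2 or 3. It was 0 with the slide as a block and 0 with only the arrays compared.

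None of the named list members passed over all genes in watered shoots. Nitrate genes had a median of 1.03 with 3 of 5 higher adjusted over the list alone, NIA1 at 1.37 ± 0.23 (adjusted p = 0.0745), and the list had adjusted p = 0.00331, and adjusted p = 0.367 with an estimated correlation. The cell cycle median was -0.17 with 3 of 16 lower adjusted over the list alone (adjusted p = 0.000769, and adjusted p = 0.506 with an estimated correlation). The LEA median was -0.25 with 4 of 18 lower adjusted over the list alone (adjusted p = 0.00882, and adjusted p = 0.556 with an estimated correlation). The jasmonate median was 0.47 with 0 of 20 adjusted over the list alone (adjusted p = 0.00213, and adjusted p = 0.611 with an estimated correlation). The salicylate median was 0.41 with 0 of 14 adjusted over the list alone (adjusted p = 0.0228, and adjusted p = 0.774 with an estimated correlation). The aquaporin median was -0.19 with 0 of 19 adjusted over the list alone (adjusted p = 0.0414, and adjusted p = 0.774 with an estimated correlation).

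NIC3OX and WT were compared in drought shoots, which by the sample labels also differed in the length of drought. MBF1C, a heat stress coactivator, fell by 1.45 ± 0.18 (adjusted p = 0.0153) in NIC3OX, and the chaperone HSP101 fell by 0.97 ± 0.10 (adjusted p = 0.0144). FLP1 fell by 1.78 ± 0.25, EXLA1 by 1.97 ± 0.41 and ARGAH2, an arginase, by 1.54 ± 0.28. P5CS1, which makes proline, rose by 0.72 ± 0.13 (adjusted p = 0.0298), and HB7 rose by 0.89 ± 0.19 (adjusted p = 0.0425). The sucrose transporter genes SUC8 and SUC6 were at least 3.84-fold and 4.61-fold higher, and PER4 at least 3.24-fold higher, none of them well above background in WT. MLO12 rose by 2.22 ± 0.36. VGDH2 was not well above background on NIC3OX shoot drought replicates 1 and 3, while it was on all 3 WT arrays.

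LEA and dehydration genes fell for 3 of 18, or 9 adjusted over the list alone, ERD14 by 0.39 ± 0.07 (adjusted p = 0.00149, and adjusted p = 0.506 with an estimated correlation). Drought transcription factors rose for 1 of 16, or 3 adjusted over the list alone (adjusted p = 0.000931, and adjusted p = 0.506 with an estimated correlation). Proline genes rose for 1 of 5, or 3 adjusted over the list alone (adjusted p = 0.0169, and adjusted p = 0.352 with an estimated correlation). Heat shock genes fell for 1 of 8, or 3 adjusted over the list alone (adjusted p = 0.00443, and adjusted p = 0.506 with an estimated correlation). Cuticular wax genes fell for 1 of 8, also adjusted over the list alone, KCS1 by 1.22 ± 0.24 (adjusted p = 0.00535, and adjusted p = 0.562 with an estimated correlation). The jasmonate median was -0.52 with 0 of 20 passing, or 1 fallen adjusted over the list alone (adjusted p = 0.00213, and adjusted p = 0.611 with an estimated correlation). The PYR/PYL median was -0.42 with 0 of 9 passing, or 5 fallen and 1 risen adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.524 with an estimated correlation). The cell cycle median was -0.11 with 0 of 16 passing, or 3 fallen adjusted over the list alone (adjusted p = 0.0246, and adjusted p = 0.62 with an estimated correlation).

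The test called 559 of 22198 genes in drought shoots, 126 higher and 433 lower, with 4251 at an unadjusted p under 0.05. The count was 0 without NIC3OX shoot drought replicate 3, 71 without replicate 1 and 113 without replicate 2 of that group, and 98, 172 and 29 without WT shoot drought replicates 1, 2 and 3. It was 200 with the slide as a block, 112 with no filter, 14 with only the arrays compared, and 2000 with all 24 arrays in 1 fit. None of the 20 genes ranked by size kept its call whichever array was left out.

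The interaction in shoots, which by the sample labels also carries the length of drought, had no gene past the limma test among 22198, against 2140 at an unadjusted p under 0.05, and the smallest adjusted p was 0.341. HSFA2 had an interaction of -2.30 ± 0.46 and HSP101 of -0.88 ± 0.15 (both adjusted p = 0.341), and AOC1 of -2.59 ± 0.73 (adjusted p = 0.405). Jasmonate genes had a mean of -1.06 with 4 of 20 lower adjusted over the list alone (adjusted p = 1.52e-07, and adjusted p = 0.419 with an estimated correlation). Heat shock genes had a median of -1.26 with 2 of 8 lower adjusted over the list alone (adjusted p = 8.83e-05, and adjusted p = 0.363 with an estimated correlation). The PYR/PYL receptors had -0.44 with 0 of 9 adjusted over the list alone (adjusted p = 0.000596, and adjusted p = 0.367 with an estimated correlation). Drought transcription factors had 0.48 with 0 of 16 adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.524 with an estimated correlation). Senescence had 0.51 with 0 of 11 adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.556 with an estimated correlation). Cuticular wax had -0.52 with 1 of 8 lower adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.686 with an estimated correlation). Nitrate assimilation had -0.94 with 4 of 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.038, and adjusted p = 0.518 with an estimated correlation), a call lost with the slide as a block. The count of genes was 9 without NIC3OX shoot control replicate 3, 1 without WT shoot drought replicate 2, and 68 with all 24 arrays in 1 fit.

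The drought response of WT roots was set against that of WT shoots. The receptor PYL6 had a difference of -4.62 ± 0.39 (adjusted p = 7.01e-07), more negative in roots, and the reductase FRO4 of -6.22 ± 0.88. The transcription factor NAC019 had 3.12 ± 0.33 and the dehydration gene RD29B 4.24 ± 0.69, both more positive in roots. HSFA2 had -2.49 ± 0.43 and AOS -1.81 ± 0.30. All of these were well above background on all 12 WT arrays. MRN1 and NIC3 passed too, but neither was well above background on WT shoot arrays, so no difference is given.

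Clade A PP2C genes were more positive in roots for 8 of 9, also adjusted over the list alone (adjusted p = 1.32e-06, and adjusted p = 0.104 with an estimated correlation). Drought transcription factors were so for 10 of 18, or 12 adjusted over the list alone (adjusted p = 1.4e-06, and adjusted p = 0.104 with an estimated correlation). LEA and dehydration genes were so for 10 of 20 with 1 the other way, or 11 and 1 adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.288 with an estimated correlation). Suberin genes were so for 3 of 11, or 5 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.443 with an estimated correlation). Antioxidant enzymes were so for 7 of 20 with 2 the other way, or 8 and 2 adjusted over the list alone (adjusted p = 0.0356, and adjusted p = 0.288 with an estimated correlation). More negative in roots were 6 of 10 PYR/PYL receptors, or 7 with 1 the other way adjusted over the list alone (adjusted p = 6.45e-06, and adjusted p = 0.104 with an estimated correlation). So were 4 of 9 heat shock genes, or 6 adjusted over the list alone (adjusted p = 0.00197, and adjusted p = 0.288 with an estimated correlation). Jasmonate genes were so for 5 of 20 with 2 the other way, or 6 and 2 adjusted over the list alone (adjusted p = 0.0348, and adjusted p = 0.586 with an estimated correlation). Nitrate genes were so for 2 of 5, also adjusted over the list alone (adjusted p = 0.0356, and adjusted p = 0.288 with an estimated correlation). The test called 3972 of 24119 genes, 2071 more positive and 1901 more negative in roots, with 7457 at an unadjusted p under 0.05. Across genes the root and shoot changes had r = 0.131, and 550 higher and 450 lower calls were shared, against 201.7 and 212.6 for independent lists. Another 99 genes were called higher in roots and lower in shoots, and 151 the other way round.

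**Figure D2:**
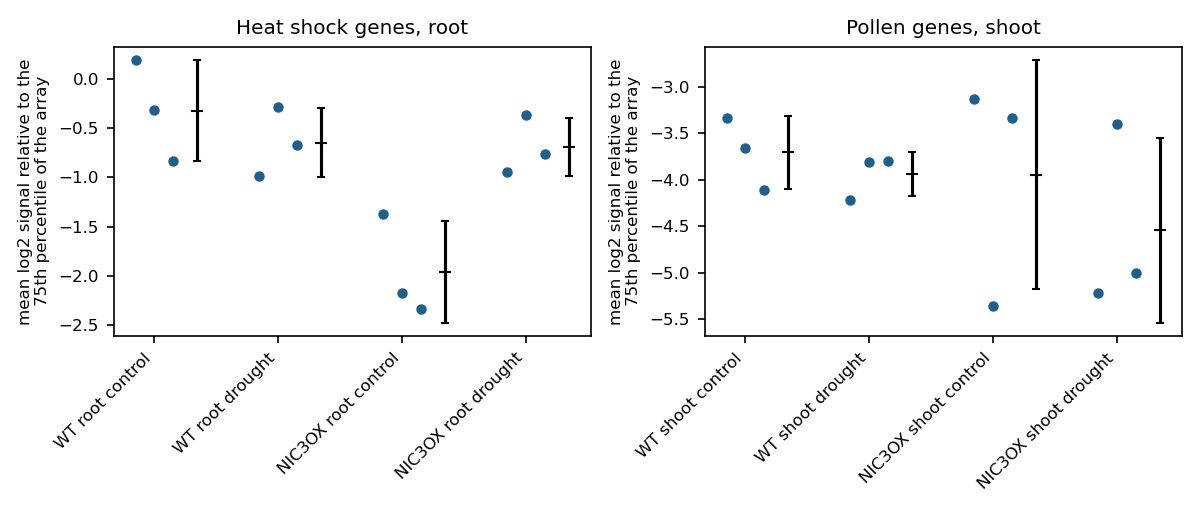
Mean signal of 9 heat shock genes on the root arrays and of 19 pollen genes on the shoot arrays (vertical axis, log2 relative to the 75th percentile of each array; horizontal axis, the groups). Points are arrays and the bars beside them give the mean and SD of 3 arrays. In control roots the NIC3OX heat shock means ran from -2.33 to -1.37 and the WT means from -0.83 to 0.19.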

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

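The tests of the value table and of the sequence tag probe and the count among equal exchanges in this part were chosen only after the result was seen, while the splits of the arrays were planned and the expectation for each was written down afterwards.

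The response of WT to drought differed between roots and shoots for 3972 genes in a test of the difference itself. Relabelling root and shoot within each condition gave as many genes in 12 of 100 splits, the real one included, and the highest other count was 16322. That is several times the real count and points to a structure of the samples: 11 splits, in which the numbers of arrays exchanged in control and drought differed by 2, gave 15569 to 16322, because the difference between organs then enters the contrast. Those splits are no measure of chance for this comparison. Among the splits that exchanged as many arrays in both conditions, a choice made after the counts were seen, 1 of 43 gave as many genes as the real 3972, the real one itself, and the highest other count was 0. There the difference between organs enters the spread within groups and leaves few calls whatever the responses, so neither set of splits decides on chance.

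In roots, the interaction of genotype and drought passed the test for RTFL11, at -1.19 on the log2 scale, and for AT2G03250. The fitted value of the latter, -2.24, is no measured size, since it was well above background on 0 control root arrays of either genotype and part of the value is a difference between background signals. Relabelling the genotype within each condition gave as many genes in 3 of 100 splits, the real one included. That share is under 0.05, although the highest other count was 3 against the real 2, and the calls were lost with the slide as a block. The genotype difference enters the contrast where unequal numbers of arrays were exchanged, and the spread within groups elsewhere. The share therefore does not decide on chance. By the sample labels, drought was longer on some NIC3OX arrays than in WT, which the interaction would also carry.

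A probe for an expressed sequence tag, not named by a locus, was higher in NIC3OX in every comparison of genotypes. It was well above background on all NIC3OX arrays, and on WT arrays only on 2 of the 3 drought roots. The fitted values, 4.43 in control roots, 3.64 in drought roots, 5.50 in control shoots and 6.00 in drought shoots on the log2 scale, are therefore no exact sizes. They stand for at least 16.4-fold, 10.8-fold, 23.7-fold and 19.5-fold differences in the same order. The gene behind the tag is not named in the files.

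Signal was also found among the probes not named by a whole locus, which no comparison above uses. They include the sequence tag and also probes for exons, introns or junctions of annotated loci, 502 of 19708. Of these 19708 probes 6882 were tested in roots and 7143 in shoots. In the WT drought response of roots 1110 passed the test, against 8219 of 22347 genes named by a locus. In that of NIC3OX 1262 passed, with 39 between genotypes in control roots and 1 in drought roots. In shoots the counts were 203 for the WT drought response, 12 for NIC3OX, 5 between genotypes in control shoots and 5 in drought shoots. The sequence tag is 1 of the calls in each comparison of genotypes, and in drought roots no other probe of this kind passed.

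All 24 columns of the deposited value table matched the array of another sample, and 24 of 24 matched an array of the other organ. The match was r = 1.0 at 4 decimals for the matched array, computed from quantile-normalized and centred scanner values, against at most 0.903 for any other array. A candidate explanation is that columns were filled in the order of positions on the slides, and 24 of 24 columns matched the array at their place in that order. Scanner files deposited under the wrong samples are argued against, since 24 of 24 scanner files had organ markers that fit their organ label, and 0 of the table columns did. The genotype and condition labels of the scanner files are not tested by organ markers, and no biological explanation was tested.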

How the results depend on the processing

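The pollen covariate, the arrays without VGDH2 signal left out, and the gene lists with each array left out were chosen only after the data were seen. Without the arrays that lacked VGDH2 signal, NIC3OX drought shoots kept 1 array and NIC3OX control shoots 2. The lone array is assumed to vary like the other groups. The NIC3OX shoot drought count given below without the arrays that lacked VGDH2 signal compares this lone array. That count therefore does not show whether the response depends on the arrays left out. The other counts that compare the lone array are not given. With so few arrays, the low count between genotypes in control shoots does not show that the result depends on the arrays left out. The value table was not run as an alternative: each column holds another sample, and reassigning the columns by their matches was not tried. Both root drought responses kept their counts within 1.5 times under every alternative run, with ranges of 6433 to 7626 and 7272 to 9459 when 1 array was left out, and so did the comparison of WT roots with shoots (3141 to 3973). The NIC3 difference in control roots stayed between -0.17 and -0.05. Scaling moved the median of all genes by under 0.1. The cause was not tested for the changes below. Only the arrays compared leave fewer arrays to estimate the spread, no filter tests more genes, and leaving out an array leaves fewer arrays. Some counts rose with an array left out, as from 284 to 463 between genotypes in control roots. Groups also varied unequally. An array's mean correlation with its group was 0.983 to 0.988 in NIC3OX control roots and 0.993 to 0.994 in NIC3OX drought roots. It was 0.975 to 0.977 in NIC3OX control shoots and 0.987 to 0.99 in WT control shoots. NIC3OX shoot control replicates 1 and 3 correlated less on average with their own group than with other shoot groups. The values were 0.9754 against 0.9771 and 0.977 against 0.9811. So did NIC3OX shoot drought replicate 2, with 0.9778 against 0.9811. For each of these arrays the most similar array belonged to a WT group.

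In control roots the genotype count was 17 with no filter, 0 with only the arrays compared, 157 with all 24 arrays in 1 fit, and 14 to 463 with 1 array left out. In drought roots it was 1 with normexp, 1 with quantile normalization. The root interaction count was 0 with normexp, 0 with quantile normalization, 0 with no filter and 0 to 4 with 1 array left out. It was 1 with the strict filter and 1 with all 24 arrays. With all 24 arrays the gene called was neither RTFL11 nor AT2G03250. The WT shoot drought count was 1494 with no filter, 4787 with all 24 arrays and 1099 to 2152 with 1 array left out. With normexp 1037 of its calls were higher and 716 lower. The NIC3OX shoot drought count was 276 with normexp, 188 with no filter, 0 with only the arrays compared, 1247 with all 24 arrays, 672 with the pollen covariate, 13 without the arrays that lacked VGDH2 signal, and 125 to 560 with 1 array left out. In control shoots the genotype count was 9 with normexp (1 higher, 8 lower), 22 with quantile normalization (10 higher, 12 lower), 7 with no filter, 37 with the strict filter, 0 with only the arrays compared, 596 with all 24 arrays, 1 with the pollen covariate, 0 without the arrays that lacked VGDH2 signal, and 0 to 393 with 1 array left out. In drought shoots it was 112 with no filter, 14 with only the arrays compared, 2000 with all 24 arrays, and 0 to 172 with 1 array left out. With quantile normalization 172 of its calls were higher and 355 lower. The shoot interaction count was 68 with all 24 arrays and 0 to 9 with 1 array left out.

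With the replicate number, which is the slide, as a block, the counts were 0 for the root interaction, 248 for the NIC3OX shoot drought response, 0 between genotypes in control shoots and 200 in drought shoots; the other counts of genes stayed within 1.5 times. Arrays of 1 number share a slide and a scan, and nothing in the labels pairs them further. Deviations of same-numbered arrays correlated over 0.1 in 9 of 18 pairs in roots and 7 of 18 in shoots, with medians of 0.08 and 0.061 against -0.04 and -0.011 for other pairs, and 8 of 12 and 6 of 12 arrays correlated best with their own number. The slide effect itself was called for 20 genes in roots and 17 in shoots.

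Of the gene lists, 0 of 70 calls held with camera and an estimated correlation. Fry also called 37 of the 70, with the direction not compared. Normexp kept 70 of the 70 camera calls, no filter 68, the pollen covariate 66 and quantile normalization 64. The strict filter kept 57, and some lists had too few genes left to be tested there. With 1 array left out 64 to 79 lists were called. The photosynthesis list, not called between genotypes in drought roots (median -0.05, adjusted p = 0.765, and adjusted p = 0.983 with an estimated correlation), had a median of 0.14 without NIC3OX root drought replicate 3 (adjusted p = 0.00287). No estimated correlation was run with arrays left out. With the block 65 list calls were made.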

Other observations

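The tests in this part were chosen only after the result was seen, except the splits of the arrays, which were planned and whose expectations were written down afterwards.

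Genes for floral organ identity were expressed in the shoots. All 9 listed genes, among them AP3, PI, AG and SEP3, were well above background on all 12 shoot arrays. On the root arrays AP3, PI and SHP1 were above background on all 12 as well, while AG, SEP1, SEP2 and SEP3 were on 0.

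Among NAD genes other than NIC3, AO, the aspartate oxidase of NAD synthesis, changed most in roots. It fell by 0.81 ± 0.13 in WT roots and by 0.75 ± 0.13 in NIC3OX roots under drought, and NIC1 fell by 0.31 ± 0.07 in WT roots. In WT shoots AO rose by 0.41 ± 0.11 (adjusted p = 0.0365). No NAD gene passed the test between genotypes in any condition or organ. The NAD list was called in none of the 10 comparisons within a tissue.

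Pollen transcripts varied between shoot arrays. VGDH2, at -1.05 to 1.26 on the 9 other shoot arrays, was between -7.23 and -6.85 and not well above background on NIC3OX shoot control replicate 2 and drought replicates 1 and 3, and PPME1 was likewise between -7.05 and -6.94 there. Open flowers in some of the shoot harvests may account for this: these arrays were 3 of the 3 lowest in the mean of 19 other pollen genes. The rule coded before these values were computed also asked for a gap above 1 and counted a smaller one against the explanation, and the gap was 0.79. It is left open here, a choice made after that result, because CPK34 and ANX1 were above background on 0 shoot arrays. Also, ACT4, PRF4, CPK17, STP11, ACA9 and AHA8 were above background on all 12 root arrays. A slide or scan batch is argued against, since the 3 arrays lay on 3 slides, while genotype (exact two-sided permutation p = 0.344) and drought (exact two-sided permutation p = 0.346) remain untold on 12 arrays.

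Heat shock genes were lower in NIC3OX control roots by a median of -1.86. A single deviating array is argued against, since the median was still -1.43 with the most influential array left out. A row effect common to the whole slide is argued against, since drought roots in the same rows had a median of -0.071 (SD of the members 0.22). Drought roots lay in another column, and each group kept its position on every slide. An effect of the control root positions alone therefore stays open. Another time of day at harvest stays open, since the largest difference among clock genes was 0.48 ± 0.18 (RVE8) and how far a shift in time would move them was not measured. Genotype in watered plants stays open too, with an exact two-sided permutation p = 0.1, the smallest that 10 splits can give, and so does any other difference in handling of the watered plants, which was not tested.

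NIC3OX shoot control replicate 1 and drought replicate 2 lay on the side of the other condition on the first principal component, at -35.8 and 29.8. These 2 arrays swapped could explain that, but 0 NIC3OX control shoot arrays had a mean of the clade A PP2C genes that reached that of a NIC3OX drought shoot array, so it is argued against.

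In the WT root response 1 of the 10 splits of the 6 arrays gave as many genes as the real 8219, the real one itself, and the highest other count was 0. In the NIC3OX root response it was 1 of 10 (9205 against 0), between genotypes in control roots 1 of 10 (284 against 1). In drought roots it was 10 of 10 (0 against 0), which a real count of 0 gives whatever the data. In shoots it was 1 of 10 for WT (2540 against 0), 1 of 10 for NIC3OX (427 against 189), 1 of 10 between genotypes in control (14 against 3) and 1 of 10 in drought (559 against 1). These 10 splits are too few for a share under 0.05. The 189 genes came from NIC3OX shoot control replicates 1 and 3 with drought replicate 2 against the rest, the same arrays that had VGDH2 signal. In the shoot interaction 100 of 100 splits gave as many genes as the real 0, which a count of 0 gives whatever the data, and the highest other count was 10, so these splits are uninformative there.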
